A study of Homo sapiens with 2 samples.

How the data were processed

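Total RNA of SW620 cells was depleted of ribosomal RNA, digested with RNase R, which degrades linear RNA and leaves circles, fragmented and made into amplified libraries, per the labels' protocols. There were 2 libraries, 1 of cells given HD-SB at 1 mg/mL for 24 h and 1 control. FastQC, HISAT2 2.1.0 and the build GRCh38 are named in the submitters' processing notes, without a role. The circRNA caller, its filters and any removal of duplicate reads are not given in the sources used here. Copies made by amplification may therefore be counted more than once.

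The deposited values are called TPM per the file headers, but they behave as CPM, the count of reads per 1000000 back-splice reads of the same library as deposited by the authors. Each column added up to 1000000, and 100% of listed values were whole multiples of 1 step per library, within 0.01 of a step, whatever the length of the circRNA. The step was 10989 CPM in the control and 86.4 CPM in HD-SB, which gave 91 and 11570 reads. The smallest listed value was 2 reads in both. The value 0.001 stood for circRNAs not listed in a library and was treated as not listed, that is 0 or 1 read, so the reads of unlisted circRNAs are missing from both totals. At this depth 1 read in the control is worth over 100 times one in HD-SB, and a control share is known only to several percentage points.

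Of the 1409 circRNAs with a host gene in the GENCODE 29 annotation of GRCh38, 1134 (80.5%) did not lie inside that gene. Coordinates are therefore printed as deposited with no build, no exon, intron or UTR was assigned, and exonic and intronic classes, spliced length and sites of miR-204-5p, planned before the data were examined, were not run. Span is the end minus the start plus 1 in the table's coordinates. Of 1162 distinct host names, 1067 were current symbols and 51 were matched as older symbols. There were 108 circRNAs with several host names, 22 with small-RNA names alone, 5 with none and 4 in spreadsheet date form. The circRNA hsa_circ_0039933, named in the title of the series, was not analysed here.

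With 1 library per group no test across circRNAs was made and no p-value is given. The planned ratio was log2((HD-SB + 172.861)/(control + 172.861)) in CPM, the pseudocount being the 5th percentile of listed values, over circRNAs with a mean of both libraries at or above 216 CPM, the median. A fold on that scale understates the change of low circRNAs, and for a circRNA listed in one library it is set by the pseudocount. Folds printed in the text are ratios of read shares for circRNAs listed in both, with a Clopper-Pearson interval conditional on the sum of both reads, and these compare the libraries and not the conditions. An interval with an unlisted circRNA covered both 0 and 1 read. The alternatives chosen before the data were examined were the pseudocount 4 times larger and smaller, median-ratio scaling, no filter, a stricter filter (top 25% of means), circRNAs in both libraries alone, 1.5-fold and 4-fold thresholds, 1 value per host gene, HD-SB thinned to the control reads and the top 50 circRNAs. A pseudocount of 0.5 read and the interval as a rule were added after the data were seen.

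Because a circRNA enters the control list only with 2 reads, ratios of listed circRNAs lean towards the control. This was checked with 1000 draws of 266 control reads from the HD-SB composition, the number at which listed reads matched the control, which listed a mean of 34.0 circRNAs. A second set of draws, 226 reads matched on the host GC of the control reads in 5 bins of HD-SB circRNAs, was used for the host gene lists. All these draws were added after the data were seen. The interval rule was also tested on simulated data. In that test on counts drawn from the HD-SB composition, with 266 control reads and nothing changed, the interval called a mean of 22.9 of 33.8 listed circRNAs lower and none higher. With 100 circRNAs raised and 100 lowered 8-fold at that depth, it called 0% of the raised and 20.9% of the lowered. At 11570 reads in both libraries it called 30.5% of the raised, 94.1% of the lowered and a mean of 45.8 unchanged circRNAs higher (at most 58). The changed control composition was rescaled to its total, so the shares of unchanged circRNAs shifted as well. Calls among them are therefore not all errors, and 8-fold is the change before rescaling. With nothing changed, a mean of 12.6 was called higher and 12.1 lower of 1428 circRNAs. The list percentile, run on 800 simulated values, lay above the central 95% for 20 of 20 lists of 40 members shifted by 1 log2 unit and for 0 of 20 unshifted lists, of which 3 lay below it. Those values were drawn independently of the mean level, unlike the ratios here. The simulation therefore does not show what the percentile can detect in these data.

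CircRNAs were named by a rule fixed before the data were examined. It took the 8 highest and the 8 lowest ratios among those in both libraries, the 4 most abundant listed in one library only, the 6 most abundant by mean, and up to 3 of each host gene list with the highest mean. Of the circRNAs that the rule names, 2 are not reported here. The 18 lists were fixed at the same time: Wnt/beta-catenin, MAPK and PI3K-AKT, and TGF-beta and Hippo signalling, cell cycle and mitosis, DNA replication and repair, apoptosis and p53, chromatin regulators, RNA splicing and RNA binding, cell adhesion, cytoskeleton and EMT, ubiquitin ligases and proteases, ER stress and integrated stress response, oxidative stress and xenobiotic metabolism, lipid and cholesterol metabolism, widely studied circRNA hosts, intestinal epithelium, and markers of fibroblasts and smooth muscle, leukocytes, and endothelial and neural cells. The median ratio of a list with at least 5 circRNAs past the filter was placed among 10000 random lists of the same size matched on deciles of mean level. For circRNAs in HD-SB only, ratio and mean level are the same quantity, so this percentile mostly tells which lists hold control circRNAs. Host GC content was taken from the longest GENCODE 29 transcript of the host, found for 96.9% of control and 96.0% of HD-SB circRNAs. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.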

Results

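Circular RNAs (circRNAs), closed loops made when a downstream splice donor joins an upstream acceptor, were measured in SW620, a human colorectal cancer cell line, with and without the herb pair of Hedyotis diffusa and Scutellaria barbata (HD-SB). The treated cells received 1 mg/mL for 24 h. There was 1 HD-SB library and 1 control library, so no value below has a replicate error, and a difference between the libraries is not a tested effect of the herbs. The table held 1485 circRNAs. The values, converted back to reads that cross a back-splice junction, came to 11570 reads on 1475 circRNAs in the HD-SB library and to 91 reads on 32 circRNAs in the control library, a 127.1-fold difference in listed reads. A circRNA needed 2 reads to be listed in either library. Intervals below are 95% Clopper-Pearson intervals and cover counting error only, since amplified reads are not independent molecules. Positions are printed as the table gives them, in a genome build that was not established.

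The most abundant circRNA of the HD-SB library came from GCN1L1, which encodes an activator of the amino acid starvation response (hsa_circ_0000448, chromosome 12, 120592774 to 120593523), with 373 reads or 32239 CPM (counts per 1000000 back-splice reads). It was followed by ATXN7, a subunit of the SAGA transcription coactivator (hsa_circ_0007761, 211 reads, 18237 CPM), LRP5L (hsa_circ_0003102, 142 reads, 12273 CPM), and RBM33, an RNA-binding protein (hsa_circ_0001772, 136 reads, 11755 CPM). A locus on chromosome 15 from 91911481 to 91911831 that carried only small-RNA names had 127 reads. In the control library, circRNAs of RNF13, an E3 ubiquitin ligase (hsa_circ_0001346, chromosome 3, 149563798 to 149639014, 6 reads), RBM33 (5 reads) and MAN1A2, a Golgi mannosidase (hsa_circ_0000118, chromosome 1, 117944808 to 117963271, 5 reads), had the most reads. The 10 most abundant circRNAs held 42.9% of control reads (32.5 to 53.7) and 13.1% of HD-SB reads (12.5 to 13.7). Draws of control reads from the HD-SB composition, described with the ratios, gave 46.8% (37.6 to 59.0 in their central 95%), so the control share was within what listing at this depth gives.

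**Figure D1:**
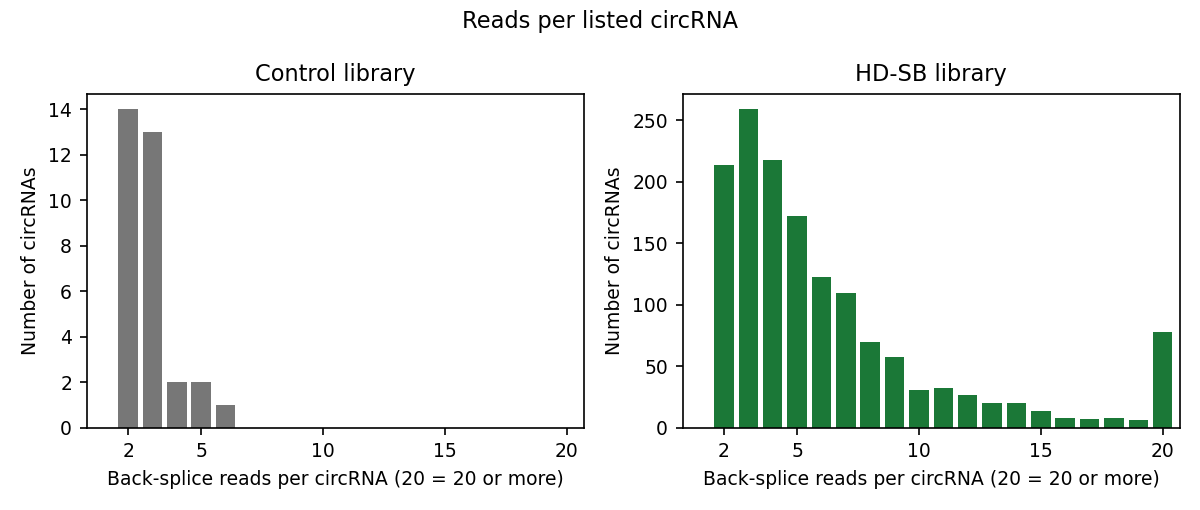
Number of circRNAs (y axis) by back-splice reads per circRNA (x axis, 20 standing for 20 or more) in the control library (left, grey) and the HD-SB library (right, green), on separate y axes. The control library had 14 circRNAs with 2 reads and 13 with 3, and its highest value was 6, while the HD-SB library had 214 with 2 reads, 259 with 3 and a highest value of 373.

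The comparison of treated with untreated cells asks which circRNAs differ after HD-SB. The libraries shared 22 circRNAs, 1453 were listed in HD-SB only and 10 in the control only. GCN1L1, ATXN7, LRP5L and the chromosome 15 locus were the 4 most abundant of those listed in HD-SB only. The 10 listed in the control only were RNF13 with 6 reads, CTBP2, a transcriptional corepressor (hsa_circ_0005418), DCAF6 (hsa_circ_0009109), AFF1 (hsa_circ_0001423) and DNAH14 (hsa_circ_0016601) with 3 reads each, and DYRK1A, BACH1, MPP6, UBAP2 (hsa_circ_0001851) and HDAC4 with 2 reads each. DNAH14, DYRK1A, BACH1, MPP6 and HDAC4 lay outside the rule for named circRNAs and were added after their values were seen. These 10 carried 28 of the 91 control reads, or 30.8% (21.5 to 41.3).

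All 22 shared circRNAs took a smaller share of reads in HD-SB than in the control, by 2.16-fold to 212-fold with a median of 24.6-fold. At the near end were CAMSAP1, which binds microtubule minus ends (hsa_circ_0001900, 2 control and 118 HD-SB reads, 2.16-fold, 0.258 to 7.96), and RBM33 (54945 against 11755 CPM, 4.67-fold, 1.49 to 11.2). UBAP2 (hsa_circ_0001847) had 3 control and 59 HD-SB reads, a 6.46-fold ratio (1.30 to 19.8), RSRC1, a splicing-related protein (hsa_circ_0001355), had 4 and 68, a 7.48-fold ratio (1.98 to 20.04), and the zinc finger gene ZKSCAN1 (hsa_circ_0001727) had 3 and 33, an 11.6-fold ratio (2.27 to 36.8). A host that the table gives in spreadsheet date form, 9-Sep (hsa_circ_0005320), had 2 and 32 reads, and its interval of 0.923 to 31.1 included an equal share. MRPS35 (hsa_circ_0000384, 2 and 17 reads) and PRRG1 (hsa_circ_0008077, 2 and 13 reads) were the remaining members of the 8 nearest to an equal share. At the far end were the circRNAs of MAN1A2, with 5 control and 3 HD-SB reads for hsa_circ_0000118 (212-fold, 41.2 to 1365) and 4 and 7 for hsa_circ_0000117 (72.7-fold, 15.6 to 286). SLC7A6, MIB1 and PCMTD1 (3 and 5 reads each, 76.3-fold, 11.8 to 392), SLX4IP (hsa_circ_0005704, 2 and 4 reads) and ZNF124 (3 and 7 reads) were also among the 8 farthest from an equal share.

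These ratios do not show a fall under HD-SB. When control reads were drawn from the HD-SB composition itself with the same listing minimum of 2 reads, so that nothing differed, a mean of 99.9% of the listed circRNAs had a larger control share, and the interval excluded an equal share for a mean of 23.4 circRNAs per draw (18 to 29 in the central 95% of 1000 draws), against 30 of the 32 control circRNAs observed. Of the 30 observed, 20 were shared and 10 were listed in the control only, which draws from the HD-SB composition cannot give. As a share of listed circRNAs, the 30 were 93.75%, against 55.3% to 82.8% in the draws. The observed median ratio of 24.6 lay above the 6.76 to 16.6 of those draws, and the highest ratio of 212 above 40.2 to 139. Those draws take reads as independent.

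**Figure D2:**
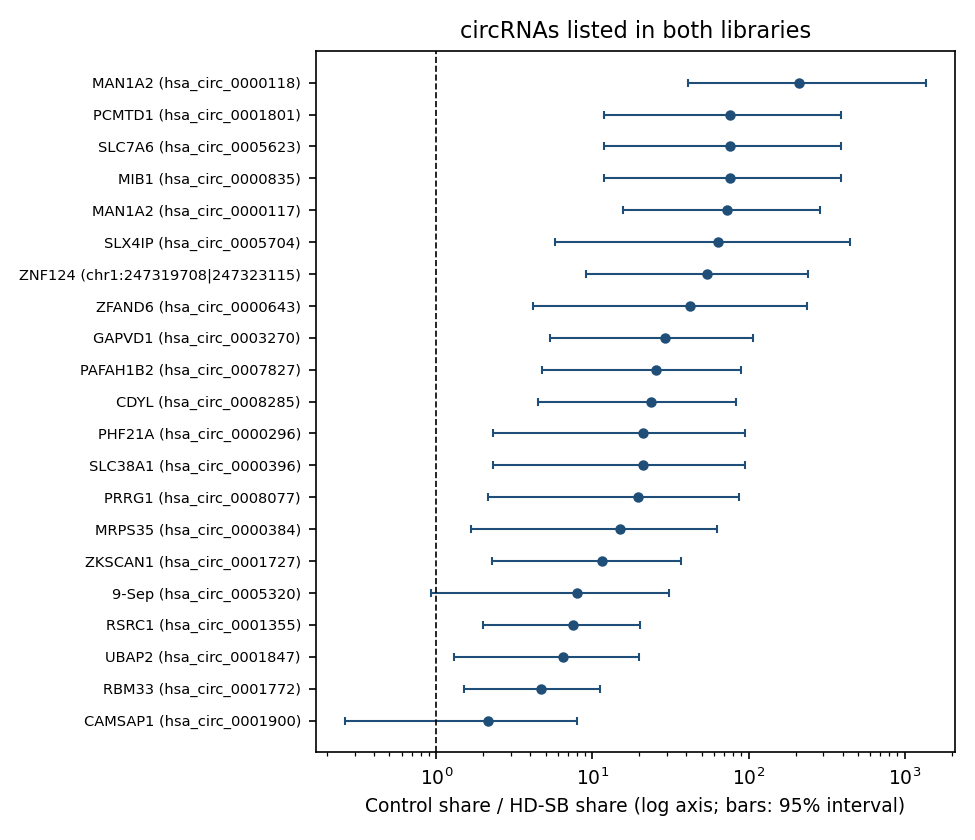
Ratio of the share of reads in the control to the share in HD-SB (x axis, log scale) for circRNAs listed in both libraries (y axis, host and identifier as in the table), all but 1 of the 22 being drawn, with 95% Clopper-Pearson intervals as bars and the dashed line at an equal share. Every point drawn lies to the right of the line, from 2.16 for CAMSAP1 to 212 for MAN1A2, and the intervals of CAMSAP1 and 9-Sep cross it, while draws with no difference between libraries also put a mean of 99.9% of listed circRNAs there.

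By the size rule fixed in advance, 797 circRNAs passed the filter on mean level, of which 765 were at least 2-fold higher in HD-SB and 32 at least 2-fold lower, on the log2(value + 172.861 CPM) scale. Every one of the 765 was listed in HD-SB only, so its direction came from setting a listed value against an unlisted one. No circRNA was higher by its interval. An HD-SB circRNA would have needed 471 reads for that against 0 control reads and 711 against 1, and GCN1L1, the highest, had 373. With a pseudocount of 0.5 read in each library, chosen after the data were seen, the counts were 4 higher and 772 lower. Scaling by the median ratio of the shared circRNAs, which multiplied control values by 0.0406, gave 771 higher and 17 lower and turned the direction of 10 named circRNAs, CAMSAP1, RBM33, UBAP2 and RSRC1 among them. As this scaling centres on the shared circRNAs, turning part of them is built into it.

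Hosts of Wnt/beta-catenin signalling gave 14 circRNAs from 7 genes, among them the Wnt co-receptors LRP6 (hsa_circ_0000378, 97 reads) and LRP5 (hsa_circ_0023179, 84 reads, and a second circRNA of 29 reads). They held 266 HD-SB reads, 2.30% (2.03 to 2.59), and no listed control read. The draws with no difference between libraries put 0% to 10.7% of control reads there, so a difference was not detectable at this depth. For the 13 other lists with no control circRNA, 0% also lay within the central 95% of draws. Cell cycle and mitosis hosts had 24 circRNAs and 211 HD-SB reads, with cyclin B1 (CCNB1, hsa_circ_0001495, 31 reads), the cohesin subunit SMC3 (27 reads) and CEP128 (19 reads). DNA replication and repair hosts had 30 circRNAs and 251 reads, with the catalytic subunit of DNA polymerase delta (POLD1, hsa_circ_0052012, 92 reads), DNA2 (18 reads) and FANCL (14 reads). MAPK and PI3K-AKT hosts had 13 circRNAs and 81 reads (RASA3 20, MAP2K1 10, AKT2 9). Oxidative stress and xenobiotic metabolism hosts had 12 and 95 reads, of which AHRR, the repressor of the aryl hydrocarbon receptor, gave 49 on hsa_circ_0005694 and 9 on another circRNA, and TIPARP gave 9. Cell adhesion, cytoskeleton and EMT hosts had 27 circRNAs and 152 reads, with 14 each for ARHGAP12 and DYNC1H1. Lipid and cholesterol metabolism had 9 circRNAs and 60 reads (OSBPL10 16, CPT1A 14, ACACA 7), TGF-beta and Hippo signalling 8 and 34 (TEAD1 9, FAT1 5, SMURF1 4), apoptosis and p53 8 and 40 (TNFRSF21 11, CASP2 6, BIRC6 6), and ER stress and the integrated stress response 7 and 28 (PDIA4 6, CANX 6, UGGT2 4).

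Hosts of the intestinal epithelium list, as fixed in advance, gave 8 circRNAs and 78 HD-SB reads, with the brush border protein villin (VIL1, hsa_circ_0058244, 18 reads), FUT8 (16 reads) and EPHB2 (16 reads). Whether each member is specific to that epithelium was not tested. Of the marker lists of other cell types, fibroblast and smooth muscle hosts gave 0 circRNAs, leukocyte hosts 1 (PTPN22, 4 reads) and endothelial and neural hosts 1 (GRIN2B, 4 reads). These counts cover the fixed lists alone, which do not hold every marker. LCK (hsa_circ_0011399, 9 HD-SB reads), for example, was not in the leukocyte list.

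In 4 lists the control had reads. Ubiquitin ligases and proteases held 11 control reads, 12.1% (6.19 to 20.6), against 195 HD-SB reads, 1.69% (1.46 to 1.94), and the 11 were the 6 of RNF13 and the 3 and 2 of the circRNAs of UBAP2. UBAP2 was in the list as fixed in advance, but it is named for a ubiquitin-associated protein rather than a ligase or protease. Chromatin regulators held 10 control reads, 11.0% (5.40 to 19.3), against 3.41% in HD-SB (3.08 to 3.75), from AFF1, CDYL (hsa_circ_0008285, 3 control and 16 HD-SB reads), PHF21A (hsa_circ_0000296, 2 and 12) and HDAC4. Widely studied circRNA hosts held 22 control reads, 24.2% (15.8 to 34.3), against 8.03% (7.54 to 8.54), with RNF13, UBAP2 and ZKSCAN1 among them. The lists share members, since RNF13 and UBAP2, with all 11 ubiquitin reads, and CDYL, with 3 chromatin reads, were also counted among the 22. RNA splicing and RNA binding hosts, led by RBM33, FTO (26 HD-SB reads) and PRPF6 (25), held 5.49% (1.81 to 12.4) against 3.89% (3.54 to 4.26), with intervals that overlapped. In the draws with no difference between libraries, the central 95% reached 5.32% for the ubiquitin list, 9.10% for chromatin regulators and 21.8% for widely studied hosts, all below the control values, again for independent reads. Each of these lists held 2 circRNAs listed in the control only, whose reads draws from the HD-SB composition cannot give. The ubiquitin value rests on 3 control circRNAs, the chromatin value on 4 and that of widely studied hosts on 7. By number of circRNAs the intervals of both libraries overlapped for ubiquitin, at 9.38% of the control list (1.98 to 25.02) against 1.76% of the HD-SB list, and for chromatin regulators, at 12.5% (3.51 to 28.99) against 3.66% (2.76 to 4.75). Against the draws, whose central 95% by number reached 6.06% for ubiquitin and 9.68% for chromatin regulators, those control values were higher. Widely studied hosts were 21.9% of the control list (9.28 to 39.97) against 4.61% of the HD-SB list (3.60 to 5.81), intervals that do not overlap, but the control value lay within the 5.13% to 22.6% of the draws. Those draws had a median host GC of 51.6%, against 41.8% in the control. In draws also matched on the host GC of the control, added after the data were seen, the central 95% reached 13.75% of reads for chromatin regulators and 26.6% for widely studied hosts, so neither control value stood apart. The ubiquitin list, 1 of 18 compared, stayed above the central 95% of these draws by reads, at 12.1% against an upper end of 10.8%. By number it did not, at 9.38% against an upper end of 10.0%. Of its 3 control circRNAs, 2 were listed in the control only, RNF13 with 6 reads and 1 of UBAP2 with 2. The draws cannot give these, so they do not decide on the excess by reads. That excess by reads includes the reads of UBAP2 and was not tested without them. Among 10000 random lists matched on mean level, the medians of the 11 lists with at least 5 circRNAs past the filter lay between percentile 3.19 (ubiquitin) and 93.1 (Wnt), so none was outside the central 95%. For circRNAs in HD-SB only, the ratio follows from the mean level that was matched. The percentile therefore had little room to move and does not show that the lists were alike.

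**Figure D3:**
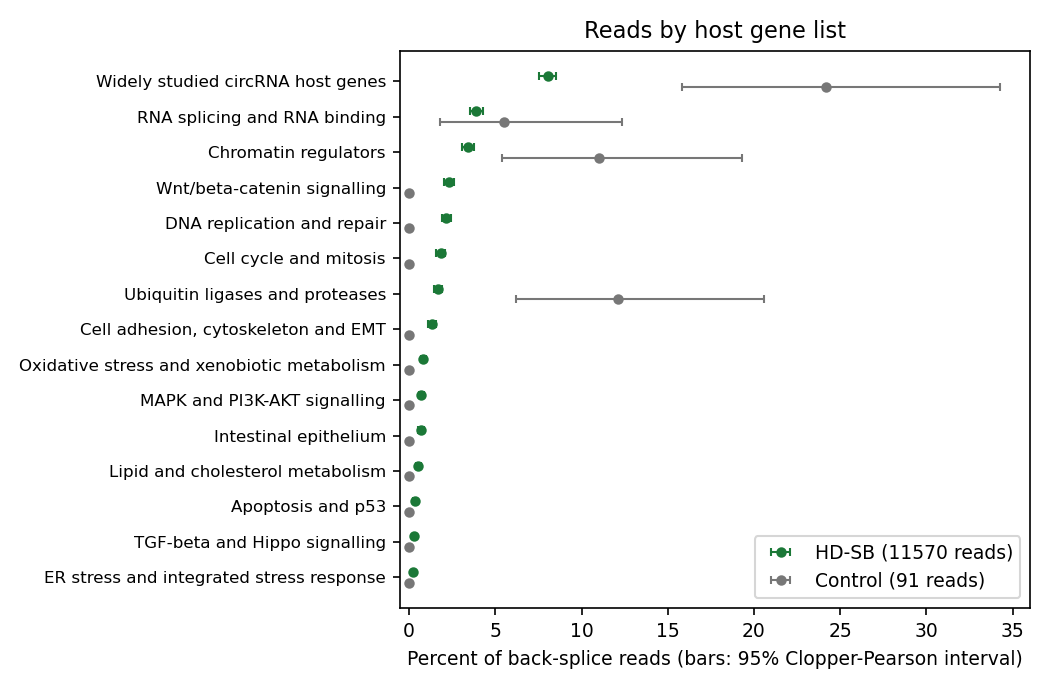
Percent of back-splice reads (x axis) by host gene list (y axis, lists with at least 5 circRNAs) in HD-SB (green) and the control (grey), with 95% Clopper-Pearson intervals as bars and no bar for lists without a listed control read. Ubiquitin ligases and proteases, chromatin regulators and widely studied circRNA hosts have intervals that do not meet, at 12.1%, 11.0% and 24.2% of control reads.

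CircRNAs that span at least 10000 bp of the genome, introns included, held 46.2% of control reads (35.6 to 56.9) and 24.3% of HD-SB reads (23.5 to 25.1). Those under 1000 bp held 15.4% (8.67 to 24.5) and 28.2% (27.36 to 29.01). The draws with no difference gave 7.68% to 29.4% for the long class and 29.03% to 55.3% for the short one, which leaves the control values outside. Those draws were not matched on host GC. They also cannot give the circRNAs listed in the control only, whose median span was 36424 bp, against 6316 bp for those listed in both. The draws therefore do not show a difference in span among the shared circRNAs. The median span was 8565 bp for the control circRNAs and 4076 bp for those of HD-SB. CircRNAs with a circBase identifier held 92.3% of control reads and 83.7% of HD-SB reads, and the draws gave 81.0% to 97.85% for the control, so this difference was within what listing gives.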

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

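The 0.5-read pseudocount and the interval rule were chosen after the data were seen. The 765 circRNAs at least 2-fold higher in HD-SB became 296 with a pseudocount 4 times larger, 1453 with no filter, 366 with the stricter filter, 0 among those in both libraries, 4 with 0.5 read in each library and 0 by the interval rule. The 32 at least 2-fold lower became 17 under median-ratio scaling and 772 with 0.5 read. The remaining counts of both directions were within 1.5 times. No filter and the stricter filter change how many circRNAs enter, and 0.5 read is worth more CPM in the control than in HD-SB, which turned circRNAs listed in HD-SB only to lower. All 765 were listed in HD-SB only, so none is left among shared circRNAs, and none reached the reads that the interval rule needs. A larger pseudocount shrinks each ratio by construction, and the cause of the fall to 17 under median-ratio scaling is its factor on the control values. Under median-ratio scaling, which multiplied control values by 0.0406, the log2 ratio turned positive for 10 of 18 named circRNAs, CAMSAP1 (3.28), RBM33 (2.31), UBAP2 (1.80), RSRC1 (1.63), 9-Sep (1.46), ZKSCAN1 (1.00), MRPS35 (0.62), PRRG1 (0.28), PHF21A (0.18) and CDYL (0.041). The factor is itself the median of the 22 shared circRNAs, whose ratios lean towards the control through listing, so about as many of them turn as not by construction and the number says nothing on single circRNAs. In HD-SB thinned to 91 reads a mean of 6.96 circRNAs was listed and 0.816 were shared, through fewer reads. Those 91 were drawn before the listing minimum of 2 reads, while the 91 of the control were counted after it. With 266 reads drawn, at which listed reads matched the control, the HD-SB composition listed a mean of 34.0 circRNAs, against 32 in the control. The top 50 circRNAs held 100% of control and 27.6% of HD-SB reads, by taking in more circRNAs. No list left the central 95% under any setting that gave a percentile, and with circRNAs in both libraries alone no list could be placed. Matching on mean level leaves this percentile little room to move for circRNAs in HD-SB only. No paired analysis was possible because each group has 1 library. The 91 control reads limit every comparison, and an HD-SB circRNA not listed in the control, at 0 or 1 read there, would need 711 reads for an interval that excludes an equal share.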

Other observations

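Several host genes gave many circRNAs in HD-SB. MAD1L1, a spindle checkpoint gene, gave 7 with 51 reads in all. RBM33, LRP5, TNS3 and the histone methyltransferase gene EHMT1 gave 6 each, with 168, 123, 48 and 27 HD-SB reads. Outside the named set, circRNAs of PVT1, a long noncoding RNA gene (hsa_circ_0001821, 93 reads), the chromatin remodeller SMARCA5 (hsa_circ_0001445, 88 reads), CCDC134 (116 reads) and PRKAR1B (98 reads) were among the most abundant of HD-SB, chosen here after their values were seen.

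In the weighing that follows, the draws of host GC for recovery by GC content were chosen before their result was seen, and the other tests after. Several models were tried in turn, so those that were not excluded are hypotheses found on the same data.

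Of the 20 most abundant circRNAs of HD-SB, 4 were listed in the control, against a median of 13 in independent reads drawn from the HD-SB composition and of 8 in draws that also matched the host GC of the control. Of 10000 such matched draws 0.41% listed 4 or fewer, which argues against independent reads recovered by host GC as matched here, in 5 bins. Host GC is that of the longest host transcript and not of the circRNA. Recovery by the GC of the circRNA itself, or within a bin, was not tested. Copies of a few molecules drawn from the HD-SB composition gave a median host GC as low as observed in 0.02% of draws, which argues against copying alone. For the 22 circRNAs listed in both libraries, copies of a few molecules with GC-dependent recovery remained open, with 83.66% of draws at or below 4. The draws of copying alone also took 22 molecules. In GC-matched draws of all 32 control circRNAs, 55.2% were at or below 4. The median of 5.5 HD-SB reads of these 32 was as low in 1.35% of those draws. The 32 include 10 not listed in HD-SB, which draws from the HD-SB composition cannot give and which lower this median by construction. It therefore does not decide on this model for all 32. For the 22 the median was 12.5 reads, with 92.81% of GC-matched draws at or below it. Copying with GC-dependent recovery is a candidate explanation for the 22 alone, reached after the other models were tried. An effect of HD-SB was not tested here, since each group has 1 library.

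The control listed 10 circRNAs that HD-SB, at 127.1 times the listed reads, did not. With independent reads from one composition, the 1453 circRNAs in HD-SB only allow a mean of at most 0.768 in the control only, so that model is argued against. A mean of 10 would take 960 control reads, and draws of that many listed at least 158 circRNAs instead of 32. Copies of a few molecules from a pool that HD-SB sampled in part cannot be told apart from a difference in composition, because circRNAs with 1 read were not listed and the unseen part of the pool has no estimate to set against the 31.25% of control circRNAs missing from HD-SB.

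Hosts of control circRNAs had a median GC content of 41.8%, against 48.4% in HD-SB, and longer spans. In 0.01% of 10000 read-weighted draws of 32 circRNAs, the smallest share they can give, the median GC was as low, which restates the pattern and leaves recovery that differs by GC content open beside a difference in composition. Against GC-matched draws the median span of all 32 stood at 97.87%, just outside the central 95%, and that of the 22 shared circRNAs at 79.12%, inside it, as it was without matching (94.33%), so their spans decide nothing. The 10 listed in the control only had a median span of 36424 bp, at or above 100% of GC-matched draws. Those draws came from circRNAs listed in HD-SB, which the 10 are not. They therefore do not decide whether lower GC accounts for the spans of the 10, or of the 32 that include them. With 1 library per group, an effect of HD-SB on which circRNAs the cells hold cannot be told apart from a difference between libraries in GC content or span.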
